A study of Homo sapiens with 4 samples.

How the data were processed

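RNA and ribosome footprints were measured in PC9 and H1933, human lung cancer cell lines grown under control conditions, with 1 library per line and kind of measurement, 4 libraries in all. Polyadenylated RNA was taken from Trizol extracts for the RNA libraries. For the footprint libraries, per the labels, cells were held in 100 µg/ml cycloheximide for 5 min, lysates were digested with RNase I at 2 U/µl for 45 min, monosomes were collected from a sucrose gradient of 7 to 47%, and protected fragments of 30 to 33 nt were sequenced. PC9 was grown in RPMI medium with 2 mM glutamine and 10% fetal bovine serum and H1933 in DMEM with 10% fetal bovine serum, so that medium and line were varied together. The second line is named as in the labels, where one protocol entry adds a digit to the name, and line identity was not tested here.

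The deposited table gave FPKM, a unit scaled by the authors for transcript length and library size, for 11779 Ensembl transcripts in 4 columns, with a gene symbol beside each. Bowtie was named per the submitters' processing notes, without a version. The genome build, the annotation release, the counting program, the counted part of each transcript, the strand setting and the treatment of reads with several matches are not given in the sources used here. Every transcript reached 1 FPKM in at least 1 library, and the smallest maximum over the 4 libraries was 1 FPKM. The rows of 2 symbols with a pair of transcripts each were summed, which left 11777 genes.

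Differences between the lines were computed as log2((PC9 FPKM + 1) / (H1933 FPKM + 1)) with a pseudocount of 1 FPKM, separately for RNA and for footprints. On this scale differences of weakly expressed genes are understated, and no fold is given against a value listed at 0. A gene entered the RNA or the footprint comparison if it reached 1 FPKM in either line in that kind of library, and entered the correlation of the RNA and footprint ratios if its mean over the 4 libraries reached 1 FPKM. Genes at least 4-fold apart (2 on the log2 scale) were counted. Translational efficiency was taken as log2((footprint FPKM + 1) / (RNA FPKM + 1)) minus the median of the line, over genes with a mean of at least 5 FPKM. The efficiency difference between the lines was taken over those genes that also had at least 1 FPKM of RNA in both lines, and genes at least 2-fold apart were counted.

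The genes named for each comparison were set by a rule. For RNA and footprints together these were the 12 genes per direction with the largest mean of both log2 differences, among genes with at least 10 FPKM in the higher line in both kinds of library and the same direction in both. For efficiency they were the 10 highest and the 10 lowest by the mean of the lines, among genes with a mean of at least 10 FPKM that lay in the top or bottom 10% in each line. For the efficiency difference they were the 10 largest per direction, at a mean of at least 10 FPKM and at least 5 FPKM of RNA in both lines. Up to 4 members of each list were named per comparison, those furthest from 0 among members with at least 5 FPKM in a library compared. Y-linked genes and the X-inactivation transcript were left out. EGFR, MET, MYC and ATF4 were named in any case, and a further gene set by the rule is not reported here. A further 10 genes of high efficiency without a HIST symbol were added after the histone genes had been seen to fill the first group. The rule, 39 gene lists with 1122 members and the first alternatives were fixed before the data were examined. Of the members, 843 had a symbol in the table, 7 of them under an older name. Gene names were compared with a RefSeq gene table for assembly GRCh38.p14, which held 10358 of the symbols as current names and 1176 as synonyms of exactly 1 gene. That table was otherwise used for which genes neighbour each other.

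A list's median was compared with the medians of 10000 random lists of the same size, matched gene by gene in 20 expression bins, and is given with its percentile among them. A list with at least 4 measured members was said to stand apart at or below percentile 2.5 or at or above percentile 97.5. With 1 library per group there were no replicates, so no p-value or error between replicates was computed, and the percentiles describe a list against other genes of the same libraries. The values of lists and correlations are across genes, and genes are not independent replicates.

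Read counts were not part of the table. Steps of whole reads were searched for among the low values. The best share of values on such steps, 0.149 to 0.175, lay below the highest of 20 shuffles in each pair of libraries, so the depth is unknown and no interval or detection limit is given.

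The steps were tested on simulated data with a small fixed noise, not estimated from these libraries, which have no replicates. The counts below check the computation and are not error rates or power for these libraries. All 63 genes simulated at 8-fold and all 69 at 16-fold were found at least 4-fold apart in RNA, as were 0 of 68 genes at 2-fold and 0 of 11018 unaltered genes. In efficiency, 65 of 65 genes at 4-fold and 56 of 56 at 8-fold were found at least 2-fold apart, with 73 of 8221 unaltered genes. Of 100 unaltered lists 7 stood apart, and 20 of 20 lists shifted by 0.5 on the log2 scale did.

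Alternatives were a pseudocount of 0.1 or 5 FPKM, no filter, a filter 5 times stricter, rescaling of each library to a total of 1000000 FPKM, centring of the ratios on their median with efficiency left uncentred, centring on a trimmed mean with 30% removed at each end, leaving out ribosomal protein genes and the 20 most abundant genes, the row with the larger mean for a repeated symbol, efficiency as the residual of a fit of footprints on RNA, random lists without matching, and the mean in place of the median of a list. Further alternatives were added after the data had been seen. Efficiency was computed without genes with a HIST symbol. Footprints of the other line were subtracted at the lowest 1% quantile of the footprint ratios (2.26% of PC9 from H1933, 1.13% of H1933 from PC9), and separately at the lowest ratio of any gene with at least 50 FPKM in the other line (0.615% and 0.228%). A uniform share above the lowest ratio would give that gene more footprints than it has, so the quantile removes too much. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.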

Results

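PC9 and H1933 are established human lung cancer cell lines. Polyadenylated RNA and ribosome-protected footprints were sequenced from each under control conditions, which gave 4 groups of 1 library: PC9 RNA, H1933 RNA, PC9 footprints and H1933 footprints. There were no replicates, and the lines were grown in different media, so a difference between them was also a difference between media. The 11777 genes summed to 422648 FPKM in PC9 RNA and 406851 FPKM in H1933 RNA, and to 915064 and 946562 FPKM in the footprint libraries. Median levels lay between 10.3 FPKM in PC9 footprints and 11.8 FPKM in H1933 RNA. The most abundant gene was GAPDH in PC9 RNA at 3248 FPKM, S100A6 in H1933 RNA at 4345 FPKM, RPL41 in PC9 footprints at 29820 FPKM and S100A6 in H1933 footprints at 49217 FPKM. Ribosomal protein genes took 17.5% and 14.9% of all FPKM in PC9 and H1933 RNA, and 21.5% and 18.3% in the footprints. The number of reads behind each value is unknown.

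The first comparison asked which mRNAs differed in level between the lines. PC9 held high levels of several genes that H1933 nearly lacked. SPP1, the secreted phosphoprotein osteopontin, stood at 398 FPKM in PC9 and 0.14 FPKM in H1933 RNA (log2 difference 8.45), and KLK5, a secreted serine protease, at 320 and 0.07 FPKM. S100A9, a calcium-binding subunit of calprotectin, stood at 714 and 2.38 FPKM (7.73), PI3, the elastase inhibitor elafin, at 342 and 0.37 FPKM, and KRT5, a keratin of basal epithelium, at 213 and 0.17 FPKM (7.51). H1933 in turn held 321 FPKM of CPE, a carboxypeptidase that processes prohormones, against 0.29 FPKM in PC9 (-7.96), 266 FPKM of BASP1 against 0.56 FPKM, and 376 FPKM of RGS2, a regulator of G protein signalling, against 1.71 FPKM.

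Among the other genes far higher in PC9 RNA were the extracellular sulfatase SULF2 (278 against 0.26 FPKM), the aminopeptidase ANPEP (249 against 0.23), the calcium-binding protein calretinin CALB2 (190 against 0.22), the actin-bundling protein LCP1 (179 against 0.14) and the transporter SLC43A3 (162 against 0.17). AKR1B10, an aldo-keto reductase, stood at 405 FPKM in PC9 and 1.2 FPKM in H1933. MAGEA4, an antigen normally restricted to the germ line, reached 195 FPKM in PC9 and was listed at 0 in H1933 RNA. Among those far higher in H1933 RNA were the membrane mucin MUC1 (195 against 0.73 FPKM), the tetraspanin TSPAN8 (135 against 0.06), the annexin ANXA10 (125 against 0.69), the GTPase RAB37 (69.5 against 0.13), the prostaglandin dehydrogenase HPGD (56.4 against 0.06), the lipid droplet protein PLIN2 (55.7 against 0.05) and the cochaperone DNAJC12 (50.6 against 0.07). AGR3, a member of the protein disulfide isomerase family, stood at 242.5 FPKM in H1933 and was listed at 0 in PC9 RNA. UBE2M, a conjugating enzyme for NEDD8 in general use by cells, was also listed at 0 in PC9 RNA, and that 0 is not read as a level.

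The receptor genes EGFR and MET differed in opposite directions. EGFR stood at 192 FPKM in PC9 and 30.0 FPKM in H1933 RNA (2.64). MET stood at 44.15 FPKM in PC9 and 1128 FPKM in H1933 (-4.64), where it ranked 22 of 11777 genes, against rank 1888 in PC9. The median RNA difference of the 10 measured genes nearest to MET was -2.41, with all 10 lower in PC9. That of the 10 genes nearest to EGFR was 0.80, with 8 higher in PC9. Whether the cells were the line named H1933 in the labels was not tested. MYC, a transcription factor of cell growth, was higher in PC9 (120 against 54.0 FPKM, 1.14).

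In all, 459 of 11581 genes were at least 4-fold higher and 648 at least 4-fold lower in PC9 RNA, together 9.56%. At 2-fold, 1580 were higher and 2236 lower. The median gene lay at -0.12 on the log2 scale, and the list medians below are read against that value. These counts depended on the pseudocount, with 1881 genes 4-fold apart at 0.1 FPKM and 389 at 5 FPKM.

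Of 34 gene lists tested in RNA, 7 stood above and 10 below random lists of matched expression. Targets of NRF2, the transcription factor of the oxidative stress response, had a median of 2.14 (percentile 100). Of 27 measured, 19 were at least 2-fold higher in PC9 and 0 lower, with AKR1B10, the glutathione peroxidase GPX2 (198 against 1.6 FPKM), the hydroxysteroid dehydrogenase AKR1C2 (81.7 against 0.34) and the aldehyde dehydrogenase ALDH3A1 (157 against 1.98) furthest from 0. Aldehyde dehydrogenases and xenobiotic enzymes, which share 2 members with other lists, had a median of 1.27 (percentile 100), with 13 of 19 higher and 2 lower. Among the higher were CYP4F11 (29.0 against 0.03 FPKM) and GSTM3 (30.8 against 0.49). ALDH1A2, an enzyme of retinoic acid synthesis, was an exception at 0.02 FPKM in PC9 and 21.2 FPKM in H1933. AKR1C2 and its AKR1C relatives are near-identical in sequence, as are several MAGEA genes, and how reads shared between copies were assigned is not given in the sources used here.

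Cancer-testis antigens had the highest median, 5.81 (percentile 100). MAGEA4, MAGEA6 (92.6 against 0.12 FPKM), CSAG1 (70.5 FPKM in PC9, listed at 0 in H1933) and MAGEA3 (63.7 against 0.15) were among the 6 of 7 at least 2-fold higher in PC9, and PRAME, listed at 0 in PC9 and at 20.1 FPKM in H1933, was the exception. Squamous and basal genes had a median of 1.21 (percentile 100) and went both ways: 8 of 14 were at least 2-fold higher, led by the keratins KRT13 (538 against 1.12 FPKM) and KRT5, and 4 were lower, including SPRR3, a component of the cornified envelope (-5.60). Mesenchymal genes had a median of 1.07 (percentile 100), with 10 of 20 higher and 4 lower. COL6A2, a collagen VI chain (5.48), the receptor kinase AXL (3.96) and the actin-binding CALD1 (3.85) were higher in PC9, and the microfibril gene FBN1 was lower (-2.39).

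Hypoxia and glycolysis genes had a median of 0.42 (percentile 98.7), with 8 of 32 at least 2-fold higher and 3 lower. GAPDH stood at 3248 FPKM in PC9 and 808 FPKM in H1933, and the lactate transporter SLC16A3 was lower in PC9 (-1.89). The mean of that list stood at percentile 95.9, within the random range. Translation initiation factors had a median of 0.41 (percentile 97.63), with 4 of 32 higher, among them EIF5 (2.16) and EIF3M (1.68), and 1 lower, EIF4A3 (-1.59). That list fell inside the random range with a pseudocount of 0.1 FPKM (percentile 97.3) and with the mean (97.08). Among all 11581 genes 1580 were higher at 2-fold, so 4 of 32 was no excess.

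On the lower side, all 26 measured interferon response genes were below 0, 21 of them at least 2-fold, with a median of -2.06 (percentile 0). The ubiquitin-like modifier ISG15 stood at 8.57 FPKM in PC9 and 130 FPKM in H1933, IFI6 at 0.43 and 44.6 FPKM, and OAS1, which makes the second messenger that activates RNase L, at 0.84 and 33.9 FPKM. Gastric, intestinal and mucous genes had a median of -1.80 (percentile 0), with 11 of 16 lower and 2 higher, and -1.07 without 7 genes listed at 0 in a library. CEACAM5, the carcinoembryonic antigen, stood at 2.82 and 91.7 FPKM and the secreted mucin MUC5B at 7.16 and 163 FPKM. EGFR family ligands had a median of -1.10 (percentile 1.79), with 5 of 9 at least 2-fold lower and 1 higher. Among the lower were EPGN (0.07 against 32.2 FPKM) and EREG (4.4 against 22.4), while TGFA lay at 0.65, short of 2-fold. With a pseudocount of 5 FPKM that list moved to percentile 12.85, and with the stricter filter to 2.81.

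Immediate early and short-lived mRNAs had a median of -0.59 (percentile 1.37), with 11 of 24 lower and 3 higher. The inhibitor of DNA binding ID3 stood at 7.9 and 93.4 FPKM, and the transcription factor JUN at 53.9 and 12.2 FPKM. Targets of ATF4 and genes of amino acid synthesis had a median of -0.51 (percentile 0.62), and went both ways. Among 12 of 37 at least 2-fold lower in PC9 were ASNS, asparagine synthetase (9.03 against 150 FPKM), DDIT4, an inhibitor of mTORC1 (58.8 against 410), and PYCR1, an enzyme of proline synthesis (31.3 against 175). Among 7 higher was PHGDH, the first enzyme of serine synthesis (101 against 4.2 FPKM). Endoplasmic reticulum folding genes had a median of -0.51 (percentile 1.15), with 8 of 25 lower, including the disulfide isomerase P4HB (-1.82) and the chaperone HYOU1 (-1.68). Cholesterol synthesis genes had a median of -0.50 (percentile 1.21), with 7 of 24 lower, such as MSMO1 (-2.32) and PMVK (-1.84), and 1 higher. Nuclear genes of oxidative phosphorylation had a median of -0.31 (percentile 0.38), with 9 of 63 at least 2-fold lower, such as COX6C (-1.99) and UQCRB (-1.50), and 2 higher. Among all 11581 genes 2236 were lower and 1580 higher at 2-fold, so that list shows no excess of genes past 2-fold.

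Against random lists not matched by expression, the ATF4 target, endoplasmic reticulum, cholesterol, immediate early and oxidative phosphorylation lists lay at percentiles 2.53, 5.62, 5.74, 2.54 and 11.1, inside the random range. ATF4 targets did so by the mean as well (9.18), and immediate early mRNAs with the stricter filter (3.95). Replication-dependent histone genes were also lower in PC9 RNA (median -1.26 over 20 genes, percentile 0.03), in libraries of polyadenylated RNA. All 32 such genes in the table had a median of 0.18 FPKM in PC9 and 1.31 FPKM in H1933. Each of the 20 reached the filter by its H1933 level, which favours that direction. HIST1H1C (5.79 FPKM) and HIST1H2BK (19.9 FPKM) also reached it in PC9. The 4 measured fibroblast markers had a median of -1.64 (percentile 0.33), which lay inside the random range with either other pseudocount and by the mean.

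Lists that did not stand apart in RNA included MAPK pathway output genes (median -0.39, percentile 10.0), although the phosphatase DUSP6 was lower (-1.77) and the AP-1 gene FOSL1 higher (2.17) in PC9. Receptor tyrosine kinases (-0.57), epithelial identity genes (-0.01), proliferation genes (-0.02), alveolar and club cell genes (-0.48), neuroendocrine genes (-0.15), MHC class I genes (-0.56), inflammatory chemokines and cytokines (-0.21) and p53 targets (-0.06) also lay within the range of random lists. With the stricter filter 5 alveolar and club cell genes stood below (-3.02, percentile 0.085), as did that list by the mean (1.2), and 5 inflammatory genes stood above (1.53, percentile 99.53), a turn in direction. Within the range were also cytosolic heat shock genes (0.44, percentile 95) and cytosolic ribosomal proteins (0.36, percentile 97.48), the latter only just. Ribosomal proteins stood apart with a pseudocount of 5 FPKM (97.81), the stricter filter (98.04), lists not matched (99.94) and the mean (99.64), and heat shock genes with lists not matched (97.64) and the mean (99.48). Other mRNAs with a 5' terminal oligopyrimidine tract lay inside as well (0.49, percentile 97.17), but stood apart with a pseudocount of 5 FPKM (97.59), lists not matched (98.99) and the mean (99.71). The rest within the range were mitochondrial ribosomal proteins (0.04), proteasome subunits (-0.11), fatty acid synthesis genes (-0.20), mRNAs with inhibitory upstream reading frames (-0.05) and mRNAs with an iron-responsive element (-0.08).

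The second comparison asked which mRNAs differed in ribosome footprints. SPP1, chosen by both kinds of measurement like the other genes of the rule, had 1348 FPKM of footprints in PC9 and 12.9 FPKM in H1933 (6.60), S100A9 3001 and 37.4 FPKM (6.29), and CPE 2.66 and 681 FPKM (-7.54). EGFR had 327 and 46.7 FPKM of footprints (2.78) and MET 44.7 and 820 FPKM (-4.17). In all, 464 of 10813 genes were at least 4-fold higher and 684 at least 4-fold lower in PC9 footprints, 10.6% of genes, with a median gene at -0.05. At 2-fold, 1765 were higher and 2188 lower. The total at 4-fold was 1964 with a pseudocount of 0.1 FPKM and 492 with 5 FPKM.

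Of 35 lists tested, 8 stood above and 9 below random lists. NRF2 targets (median 1.72, 21 of 27 at least 2-fold higher), aldehyde dehydrogenases and xenobiotic enzymes (1.31, 11 of 18 higher), cancer-testis antigens (5.07, 6 of 7 higher) and mesenchymal genes (1.02, 10 of 20 higher) stood above as in RNA. At least 2-fold lower were 0, 3, 1 and 4 members of these lists, in that order. Squamous and basal genes had a median of 0.77 (percentile 99.35, but 96.51 with a pseudocount of 5 FPKM and 93.01 by the mean), with 8 of 16 higher and 5 lower, and 0.13 without 1 gene listed at 0 in a library. All 27 interferon response genes were below 0 in PC9 footprints, 25 of them at least 2-fold (median -2.07), with ISG15 at 16.8 and 511 FPKM. Gastric, intestinal and mucous genes had a median of -2.49, with 13 of 17 lower and 2 higher.

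Some lists stood apart in footprints and lay within the random range in RNA, ribosomal proteins by a narrow margin. The efficiency difference of the fifth comparison sets footprints against RNA, over genes with enough RNA in both lines. There MHC class I genes (-0.18, percentile 5.81) and heat shock genes lay inside the random range. Ribosomal proteins stood above matched lists (0.04, percentile 99.87, but 34.8 against lists not matched and 94.03 by the mean), though not above the median of all genes (0.06). Cytosolic heat shock genes had a median of 0.68 (percentile 99.38), with 7 of 18 at least 2-fold higher and 0 lower, led by the chaperone HSP90AA1 at 5839 FPKM in PC9 and 1348 FPKM in H1933. Cytosolic ribosomal proteins had a median of 0.35 (percentile 99.6), with 11 of 77 higher, such as RPL5 (1.58), and 4 lower, such as RPS20 (-1.52). Among all 10813 genes 1765 were higher and 2188 lower at 2-fold, so that list shows no excess of genes past 2-fold. MHC class I genes had a median of -0.95 (percentile 0.28), with 8 of 16 lower, including HLA-B (10.1 against 95 FPKM, -3.11). Alveolar and club cell genes had a median of -1.23 (percentile 1.36), with 5 of 9 lower, MUC1 and HOPX among them, and 2 higher. That list lay inside the random range with either other pseudocount and either other filter. Nuclear genes of oxidative phosphorylation (-0.53), immediate early mRNAs (-1.0), endoplasmic reticulum folding genes (-0.59), cholesterol synthesis genes (-0.58) and ATF4 targets (-0.53) stood below, as in RNA. Hypoxia and glycolysis genes (0.05, percentile 59.15), translation initiation factors (0.39, percentile 95.96), EGFR family ligands (-0.90, percentile 6.81) and fibroblast markers (-1.44, percentile 4.18) stood apart in RNA and lay within the random range in footprints. These contrasts depended on the settings. With a pseudocount of 5 FPKM the EGFR family ligands stood apart in footprints (0.655) and not in RNA, and they stood apart in footprints by the mean (0.76). So did initiation factors by the mean (98.34) and fibroblast markers with lists not matched (1.94).

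Replication-dependent histone genes went the other way in footprints. Their median was 0.69 over 32 genes (percentile 99.97), with 9 at least 2-fold higher in PC9 and 4 lower, against -1.26 in RNA over the 20 genes that passed the filter there. Their mean difference in footprints stood at percentile 96.27, within the random range.

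Genes nearly silent in H1933 RNA still had footprints in H1933. Genes with a HIST symbol were left out here. There were 33 other genes with under 0.5 FPKM of H1933 RNA and at least 50 FPKM of PC9 footprints. Their H1933 footprint level had a median of 1.94% of the PC9 level, from 0.615% for SLC43A3 to 5.95% for MAL. Their RNA level had a median of 0.116%. SPP1, PI3, KRT5, KLK5, SULF2, ANPEP, CALB2, LCP1 and MAGEA4 are among these genes. The H1933 levels of the 33 genes followed their PC9 footprints across genes (Spearman rho 0.747, over genes, which are not independent replicates). In the other direction, 21 genes without a HIST symbol and nearly silent in PC9 RNA had a median of 0.576% of the H1933 footprints, against 0.0904% in RNA.

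**Figure D1:**
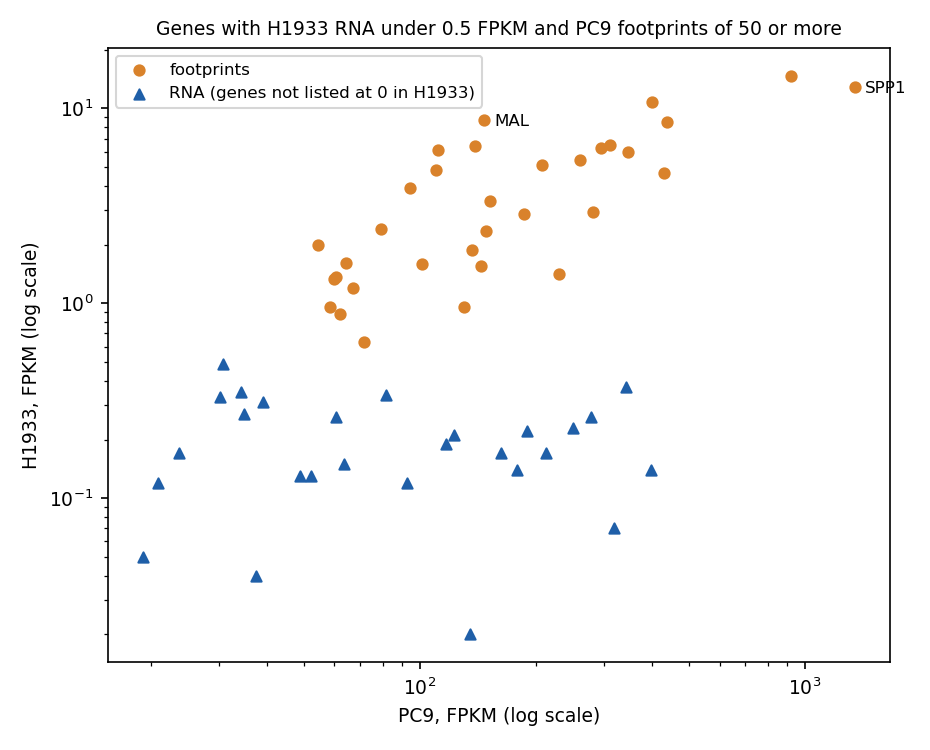
Levels in H1933 (vertical axis, FPKM, log scale) against PC9 (horizontal axis, FPKM, log scale) of 33 genes with H1933 RNA under 0.5 FPKM and PC9 footprints of at least 50 FPKM, with round points for footprints and triangles for RNA of genes not listed at 0. Genes with a HIST symbol are left out. The footprint points have a median of 1.94% of the PC9 level, with a spread from 0.615% to 5.95%, and the RNA points lie lower (median of all 33 genes 0.116%).

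The third comparison asked how far the footprint differences followed the RNA differences. Of 1078 genes at least 4-fold apart in RNA and measured in both kinds of library, 1073 had the same direction in footprints and 1062 of these were at least 2-fold apart there. At 4-fold in both kinds, 339 genes were higher and 476 lower in PC9. The 5 genes that were at least 2-fold apart in opposite directions were all histone genes, HIST1H2BD, HIST1H2AE, HIST1H2BC, HIST1H4C and HIST1H2BJ. HIST1H2BD, for example, had 0.45 FPKM of RNA in PC9 and 9.51 FPKM in H1933, with footprints of 1016 and 400 FPKM.

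Across 10915 genes the RNA and footprint log2 ratios had a Pearson r of 0.913 and a Spearman rho of 0.890. The slope of footprint on RNA ratios was 0.922 by least squares and 1.01 along the major axis. With each library rescaled to the same total the least squares slope was 0.784. The RNA libraries of the lines had an r of 0.749 with each other, and the footprint libraries 0.844.

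**Figure D2:**
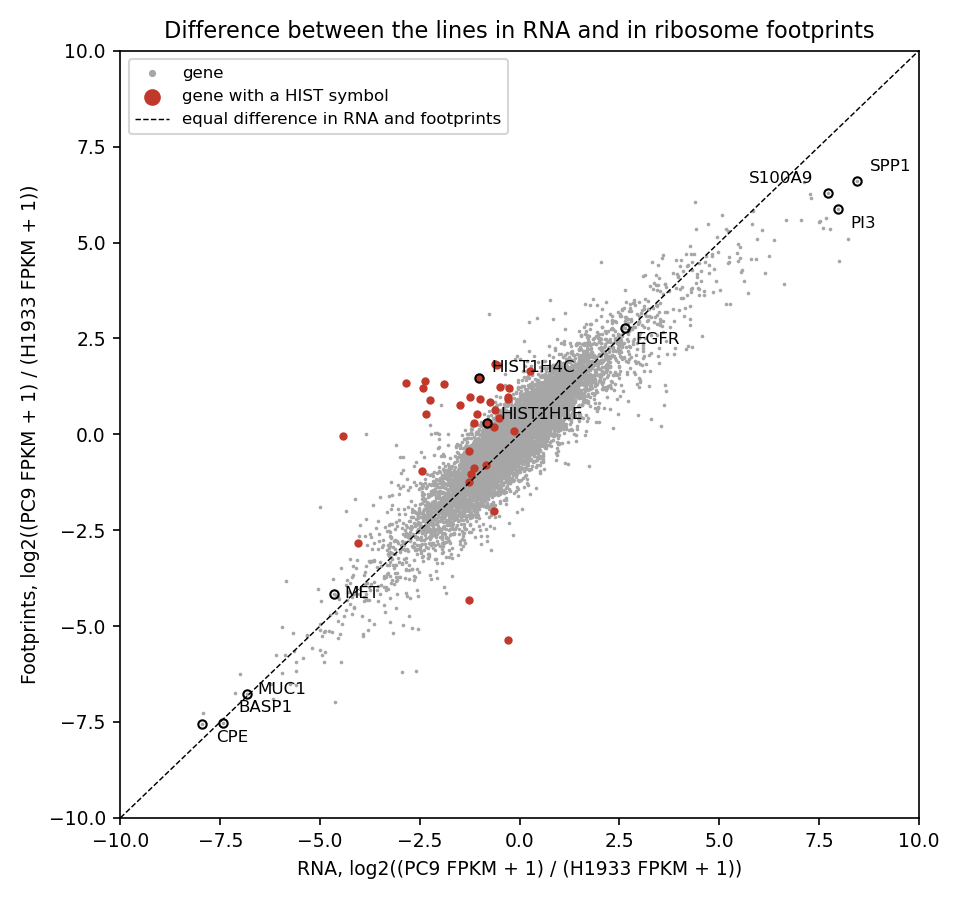
Log2 ratio of PC9 to H1933 in ribosome footprints (vertical axis) against that in RNA (horizontal axis), both with a pseudocount of 1 FPKM, for 10915 genes, with genes with a HIST symbol in red and the line of equal ratios dashed. Points run along the line (r 0.913), with SPP1 and CPE near the ends, and several histone genes above it.

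**Figure D3:**
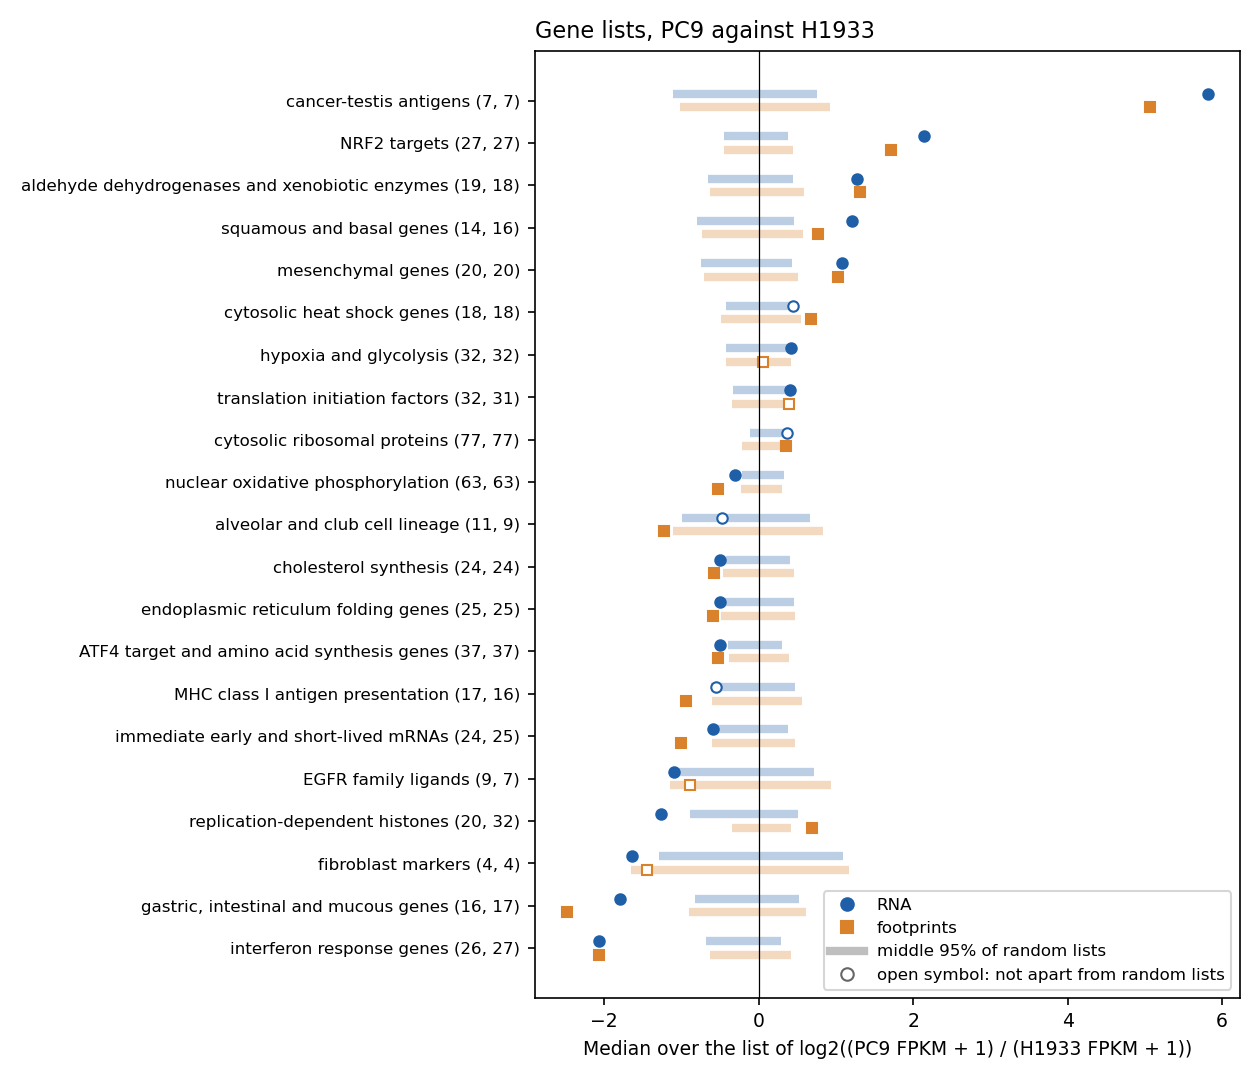
Median log2 ratio of PC9 to H1933 (horizontal axis, pseudocount of 1 FPKM) of each gene list that stood apart in RNA (circles) or footprints (squares), with the number of genes measured in each kind in brackets, bars for the middle 95% of matched random lists and open symbols for medians inside them. Cancer-testis antigens and NRF2 targets lie furthest to the right and interferon response and gastric genes furthest to the left in both kinds.

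The fourth comparison asked which mRNAs carried many or few footprints for their RNA level within each line. The counted part of each transcript is not given in the sources used here, so a ratio that differs between genes of a line also carries the length of the regions counted. Histone genes had the highest translational efficiency. HIST1H4E had 0.38 FPKM of RNA and 3226 FPKM of footprints in PC9, and 0.15 and 1033 FPKM in H1933, and lay 10.89 and 9.50 log2 units above the median gene. HIST1H2AH, HIST1H4H, HIST1H4C, HIST1H1E, HIST1H2AG, HIST1H1B, HIST1H2BI, HIST1H4I and HIST4H4 filled the other places among the highest 10. Histone genes of a class are near-identical in sequence, and the level of each gene is uncertain to that extent. The 32 replication-dependent histone genes had a median RNA level of 0.18 FPKM in PC9, where 11 were listed at 0, and 1.31 FPKM in H1933, in libraries of polyadenylated RNA. Their median footprint levels were 949 and 502 FPKM. The 7 replacement histone genes, whose mRNAs carry a poly(A) tail, had 144 and 200 FPKM of RNA and efficiencies of 1.08 and 1.46.

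Outside the histones, and chosen after their values were seen, ATP5E, a subunit of the ATP synthase, lay at 5.35 in PC9 and 5.29 in H1933, with 38.6 and 76.9 FPKM of RNA and 1987 and 3803 FPKM of footprints. The ribosomal protein genes RPL37 (5.19 and 5.15) and RPL41 (4.36 and 4.89), the copper chaperone ATOX1 (5.23 and 4.91), ENY2 (4.34 and 4.51) and the thymosin TMSB4X (4.03 and 4.52) followed. At the low end were the humanin-like genes MTRNR2L1 (-8.64 and -7.75) and MTRNR2L9, both listed at 0 in the footprints of both lines, and MTRNR2L8 at 1468 FPKM of RNA and 6.55 FPKM of footprints in PC9. These genes closely match a mitochondrial ribosomal RNA sequence and each other, so the level of each is uncertain. C19orf48 was also low (-6.28 and -5.82). MRPL30, a mitochondrial ribosomal protein, was listed at 0 in the footprints of both lines, and that 0 is not read as a level. ATF4 itself lay at -3.78 in PC9 and -2.57 in H1933.

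Nuclear genes of oxidative phosphorylation stood above random lists in both lines, with a median of 1.47 in PC9 and 1.46 in H1933 (percentile 100 in both). At least 2-fold above the median gene were 37 of 63 in PC9 and 39 in H1933, with COX7B at 4.30 and 3.68 and ATP5G3 at 3.77 and 3.51. The mRNAs with inhibitory upstream reading frames stood below in both lines (-1.50 and -1.46, percentile 0 in both), with 11 of 20 at least 2-fold below in PC9 and 15 in H1933. SLC35A4 lay at -4.81 and -4.91, the stress transcription factor DDIT3 at -2.69 and -3.60, and ATF5 at -3.27 and -2.40. MAPK pathway output genes were low in both lines (-0.69, percentile 0.45, and -0.80, percentile 0.19), with MYEOV at -3.67 and -3.10 and the ERK inhibitor SPRED2 at -1.74 and -2.20. With the stricter filter this list lay at percentiles 37.1 and 7.10. Replication-dependent histones had medians of 8.95 and 7.32.

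In PC9, endoplasmic reticulum folding genes had a median efficiency of 1.00 (percentile 98.74, but 90.03 by the mean), with the disulfide isomerase PDIA3 at 2.03. Their median in H1933 was about the same, 1.01, inside the random range (percentile 96.22, but 100 against lists not matched). Other mRNAs with a 5' terminal oligopyrimidine tract stood below in PC9 at 0.41 (percentile 0.71, but 94.42 against lists not matched). In H1933 they lay at 0.56 (percentile 3.15), below the range with a pseudocount of 5 FPKM (1.09), the stricter filter (0.98), the mean (0.27) and 2.26% of PC9 footprints subtracted (2.26), and above it against lists not matched (98.42).

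In H1933, squamous and basal genes (1.21), MHC class I genes (0.86, percentile 98.62, but 90.92 with the stricter filter and 97.18 by the mean), mitochondrial ribosomal proteins (0.81, percentile 99.3, but 97.04 by the mean), NRF2 targets (0.86, percentile 99.96) and aldehyde dehydrogenases and xenobiotic enzymes (0.63, percentile 99.45) stood above. Their PC9 medians were 0.22, 0.05, 0.77, 0.26 and 0.08, all inside the random range. In efficiency difference between the lines, the fifth comparison below, squamous and aldehyde dehydrogenase lists stood below and the other 3 lay inside the random range. MHC class I genes had a median of -0.18 there (percentile 5.81) and NRF2 targets 0.00 (48.91). MHC class I genes stood below with a pseudocount of 5 FPKM (0.89), the stricter filter (1.77) and the mean (0.13), and NRF2 targets by the mean (0.21). Mitochondrial ribosomal proteins lay only just inside in PC9 (percentile 97.28), and stood apart there in 5 alternatives, up to percentile 100 against lists not matched. NRF2 targets lay near the lower limit in PC9 (percentile 2.69), and stood below with either other pseudocount (2.35 and 2.2) and the stricter filter (0.755). Without a filter, squamous and basal genes stood above in PC9 too (98.92). The efficiency filter is a mean over the 4 libraries, so genes with little H1933 RNA could enter through PC9. KRT5 (0.17 FPKM of RNA and 8.47 FPKM of footprints in H1933), AKR1C2 (0.34 and 10.8) and GSTM3 (0.49 and 5.41) did so. Such ratios rest largely on the pseudocount, so the squamous, NRF2 and aldehyde dehydrogenase values in H1933 cannot be read as high translation. After subtraction of 2.26% of the PC9 footprints, a share above the ratio of 22 of the 33 genes described above, NRF2 targets lay at percentile 78.15 and aldehyde dehydrogenases and xenobiotic enzymes at 91.47. With 0.615% subtracted, the lowest ratio of any gene, they lay at 99.73 and 98.15. The aldehyde dehydrogenase list also lay inside the random range with a pseudocount of 5 FPKM (95.7), the stricter filter (80.25) and lists not matched (97.47), and kept its place in 5 of 9 alternatives. Receptor tyrosine kinases had low efficiencies in both lines. They stood below in H1933 (-0.77, percentile 0.88, but 4.20 against lists not matched and 5.23 without a filter), with EPHB4 at -1.59, and lay at -0.82 in PC9 (percentile 3.26, but 0.64 with the stricter filter and 2.07 by the mean). Cytosolic ribosomal proteins had a median of 0.78 in PC9 and 0.80 in H1933. The value in H1933 lay at percentile 0.1 among lists of matched expression, at 10.05 by the mean and at percentile 100 among lists not matched, so their place depends on the genes they are set against.

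**Figure D4:**
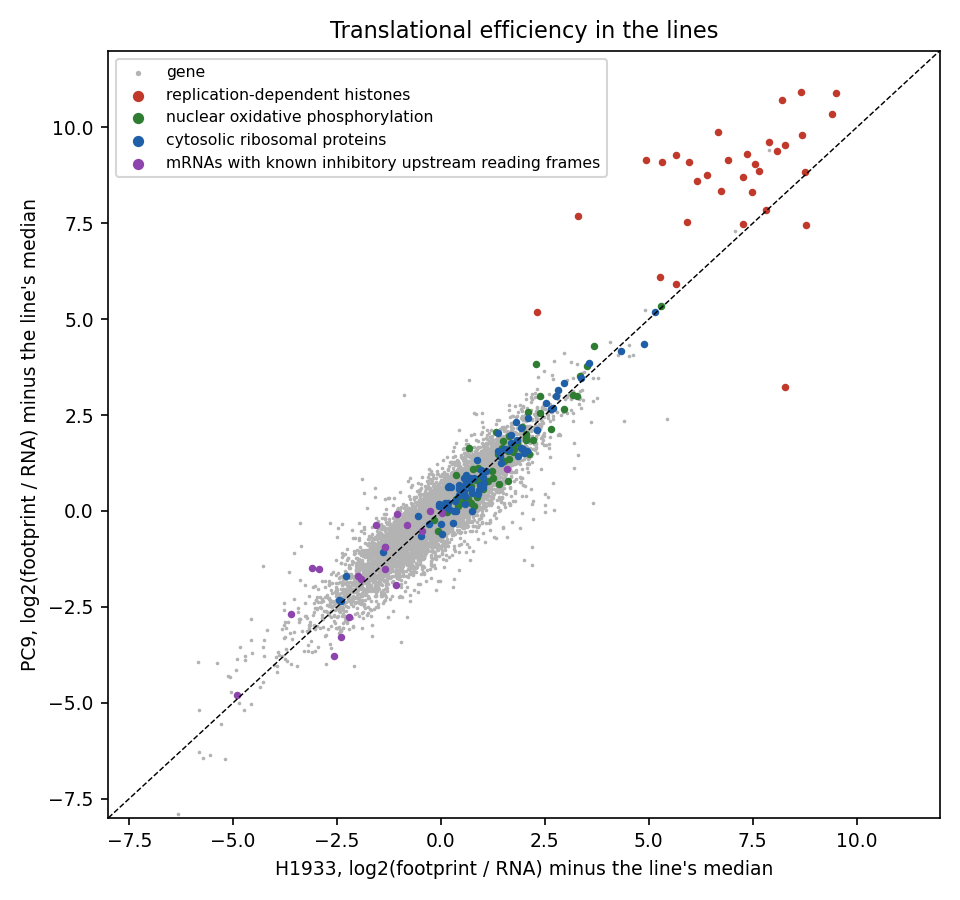
Translational efficiency in PC9 (vertical axis) against H1933 (horizontal axis), both as log2 of footprints over RNA minus the median of the line, for 8440 genes, with 4 gene lists in colour and the line of equal values dashed. Most replication-dependent histones lie above the other genes in both lines (medians 8.95 in PC9 and 7.32 in H1933), genes of oxidative phosphorylation mostly above 0 and mRNAs with inhibitory upstream reading frames mostly below 0.

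The fifth comparison asked which mRNAs differed in efficiency between the lines. Across 8440 genes the efficiencies of the lines had a Pearson r of 0.916 and a Spearman rho of 0.895, and an SD over genes of 1.26 in PC9 and 1.25 in H1933. Of 8131 genes, 152 were at least 2-fold higher in PC9 and 133 at least 2-fold lower, together 3.51%, and 20 were at least 4-fold apart. The highest differences were those of the histone genes HIST1H1C (4.40) and HIST1H2BK (2.89). HIST1H1C had 5.79 FPKM of RNA in PC9 and 145 FPKM in H1933, with 1741 and 1783 FPKM of footprints. For both histone genes the difference lay mostly in RNA, in libraries of polyadenylated RNA, so it cannot be read as a difference in ribosome load. TIMM9, a chaperone of mitochondrial protein import, followed at 2.72, with 40.3 FPKM of footprints in PC9 and 4.38 FPKM in H1933 at 17.8 and 15.0 FPKM of RNA.

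Other genes of higher efficiency in PC9 were MRPL33, a mitochondrial ribosomal protein (1.95), PVRIG (1.90), CDC26, a subunit of the anaphase-promoting complex (1.64), and AZIN1, the antizyme inhibitor (1.61, at 67.5 and 147 FPKM of RNA). C16orf74 (2.45) was listed at 0 in H1933 footprints, and both it and AC010507.1 (1.74) fell under 2-fold with a pseudocount of 5 FPKM, to 0.73 and 0.66. Higher in H1933 were the transcription factor MAFG (-1.80), the actin-binding LIMA1 (-1.79), alpha-catenin CTNNA1 (-1.64), MTRNR2L8 (-1.58), C17orf89 (-1.58), BLOC1S3 (-1.54), the filamin FLNA (-1.51), FAM195A (-1.50), CCDC85B (-1.50) and ALKBH7 (-1.50). CTNNA1 had 14.8 FPKM of RNA in PC9 and 148 FPKM in H1933, with 9.08 and 297 FPKM of footprints. ATF4 was lower in efficiency in PC9 (-1.21).

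Of 28 lists tested, 1 stood above and 6 below random lists. Cytosolic ribosomal proteins had a median difference of 0.04 (percentile 99.87, but 34.8 against lists not matched and 94.03 by the mean), with 0 of 77 at least 2-fold apart. The median over all 8131 genes was 0.06, so that list stood above lists of matched expression and not above the typical gene. Hypoxia and glycolysis genes had a median of -0.23 (percentile 0.69), with 22 of 27 below 0 and 0 at least 2-fold apart. Immediate early mRNAs (-0.22, percentile 1.7), epithelial identity genes (-0.20, percentile 1.23), ATF4 targets (-0.15, percentile 1.52) and aldehyde dehydrogenases and xenobiotic enzymes (-0.30, percentile 1.85) also stood below. The last 4 of these lay inside the random range with the stricter filter, and the last one also after subtraction of 2.26% of the PC9 footprints (percentile 5.86), but not of 0.615% (percentile 1.65). Epithelial identity genes and ATF4 targets did so with a pseudocount of 5 FPKM too (3.45 and 4.56), and epithelial identity genes without a filter (5.19). The 5 squamous and basal genes with enough RNA had a median of -1.06 (percentile 0.01). KRT13, at -3.45, had 773 FPKM of footprints in PC9 and 32.5 FPKM in H1933. Its H1933 RNA was only just past the 1 FPKM needed, so its efficiency there is uncertain. The list kept its place in 8 of 8 alternatives, subtraction at either share among them. With the stricter filter it had under 4 members and was not tested. The share of genes at least 2-fold apart was 5.22% in the least abundant and 2.52% in the most abundant of 5 abundance bins, and the total was 736 without a filter, 86 with the stricter filter, 152 with a pseudocount of 5 FPKM and 443 with each library rescaled to the same total.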

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

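Of the tests below, those of the footprints in H1933, of the histone genes and of the scaling behind MET were chosen after the result had been seen, and those of the neighbours of MET and EGFR before. Among the genes named for the efficiency difference, 7 lay above the median gene in one line and below it in the other. Among the lists that stood apart in both RNA and footprints, 1 had medians of opposite sign. With 1 library per group these differences were not tested. TIMM9 lay at 0.83 in PC9 and -1.89 in H1933, a difference of 2.72. MRPL33 lay at 0.37 and -1.57, a difference of 1.95. MAFG lay at -1.03 and 0.76 (difference -1.80), CTNNA1 at -0.95 and 0.68 (-1.64), C17orf89 at -0.58 and 1.01 (-1.58), BLOC1S3 at -1.46 and 0.08 (-1.54) and CCDC85B at -1.07 and 0.43 (-1.50). Replication-dependent histone genes had a median footprint difference of 0.695 over 32 genes and a median RNA difference of -1.26 over the 20 that passed the RNA filter.

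Genes specific to PC9 by RNA had low footprint levels in H1933 that followed their PC9 footprints. Over 2492 genes with at least 50 FPKM in PC9 the lowest H1933 to PC9 footprint ratio was 0.615%, so footprints carried from the PC9 into the H1933 library at 1 share may account for about that much and not for the 1.94% of the median gene of the 33, the rest of which stays open. PC9 cells within an H1933 culture that served for both libraries were argued against, because the lowest 1% quantile of the ratios was 0.189% in RNA (bootstrap over genes 0.0936 to 0.90%) and 2.26% in footprints (1.71 to 3.32%). Footprints too short to separate related genes stay open as a source. The footprint quantile stayed at 2.18% (1.46 to 4.54%) over 774 genes that share no symbol stem. A symbol stem does not measure likeness of sequence, and these genes were of any H1933 level, so that value cannot decide. Carry-over before or during sequencing, PC9 cells in a separate H1933 culture used for footprints alone and low translation of these genes in H1933 all stay open, and no biological explanation was tested.

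The footprint to RNA ratio of replication-dependent histone genes was high, with medians of 8.95 log2 units above the median gene in PC9 and 7.32 in H1933. Their mRNAs end in a stem-loop in place of a poly(A) tail, and selection of polyadenylated RNA is a candidate explanation. Polyadenylated replacement histone genes had a median efficiency lower by at least 5.86 log2 units in each line, which is what that explanation needs. Whether these mRNAs also carry more ribosomes cannot be told apart from it, since their median RNA level in PC9, 0.18 FPKM, is too low in such a library to give a ratio. The opposite signs of the RNA and footprint differences between the lines rest on those same RNA levels, and no biological explanation was tested.

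MET was among the most abundant mRNAs of H1933, at rank 22. A region around MET at higher copy number in H1933 may contribute, since the median RNA difference of its 10 nearest measured genes, -2.41, lay at percentile 0.185 among 10269 such windows, and their median in footprints was -2.42. CAV1, between CAV2 and MET, was near 0 in RNA (-0.15), so the neighbours were not raised alike. Runs of neighbouring genes around PDK4 (-2.54), MCM7 (-2.42) and SMURF1 (-2.33) were about as low in PC9, so such a median was not particular to the genes around MET. Whether these runs and MET belong to 1 wider region was not tested. Scaling of the libraries was argued against, because 3 other scalings moved the difference of -4.64 by at most 0.12, while a difference in MET regulation between the lines stays open and was not tested. For EGFR the same test gave percentile 92.2, which leaves a copy number difference there open, and the DNA of the lines was not analysed here.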

How the results depend on the processing

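Subtraction of carried footprints at either share and removal of histone genes were alternatives chosen after the data had been seen. The correlation of RNA and footprint ratios kept to 0.90 to 0.926 and that of efficiency between the lines to 0.893 to 0.925 under all alternatives tried. Values of named genes were followed under the other pseudocounts, no filter, the scalings and both subtractions, and not under the rest. Of these values, 1084 kept their side of the 2-fold threshold. The other 2, the efficiency differences of C16orf74 and AC010507.1, came under it with a pseudocount of 5 FPKM (0.73 and 0.66). No value of 2-fold or more turned direction. Most of these genes were picked as the most extreme, so the count is not a test of their values. Leaving out the filter cannot move their RNA and footprint ratios. Of the list values, 1176 stayed on their side of the random range, 47 moved inside it, 68 moved outside it and 1 turned: the median efficiency of cytosolic ribosomal proteins in H1933 stood at percentile 0.1 among matched lists and at percentile 100 among lists not matched. That alternative draws less abundant genes, by its construction. With a pseudocount of 0.1 FPKM, 1881 genes were 4-fold apart in RNA (744 higher, 1137 lower in PC9) and 1964 in footprints (783 and 1181), and the SD of efficiency was 1.44 in PC9 and 1.41 in H1933. With a pseudocount of 5 FPKM, 389 were 4-fold apart in RNA (184 and 205) and 492 in footprints (210 and 282), 152 were 2-fold apart in efficiency (77 and 75), and the SD was 1.02 in both lines. A larger pseudocount draws all ratios towards 0 by its construction. Without a filter, 736 genes were 2-fold apart in efficiency (373 and 363), from more genes tested, with an SD of 1.19 and 1.2. With the stricter filter, from fewer genes, 86 were (43 and 43), with an SD of 1.34 in PC9. With each library rescaled to a total of 1000000 FPKM, 443 were (220 lower in PC9) and the slope of footprint on RNA ratios was 0.784, since rescaling raises RNA values more than footprint values against the fixed pseudocount. With 2.26% of the PC9 footprints subtracted, a share above the lowest ratio of 0.615% and so too large for 1 uniform share, the slope was 1.00 and 1228 genes were 4-fold apart in footprints. With 0.615% subtracted the slope was 0.942 and 1172 genes were 4-fold apart. Without histone genes the SD was 1.14 and 1.16. Rescaling and centring moved the median gene by -0.06 to 0.12 in RNA and by 0.05 in footprints. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each line and kind of measurement had 1 library, with replicate number 1. The depth of the libraries is unknown. From the least to the most abundant of 5 bins, efficiency was at least 2-fold apart in 5.22, 3.20, 4.0, 2.58 and 2.52% of genes, and the cause was not tested.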

Other observations

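All genes and regions in this part were chosen after their values had been seen. S100A6, S100P and PSCA had high RNA and footprint levels in H1933. S100A6, a calcium-binding protein, had 4345 FPKM of RNA and 49217 FPKM of footprints in H1933, against 636 and 4632 FPKM in PC9, and ranked first in both H1933 libraries. S100P, of the same family, had 746 and 12785 FPKM in H1933, against 75.4 and 1034 FPKM, and ranked 3 in H1933 footprints, while S100A9 of that family was higher in PC9 (7.73 in RNA and 6.29 in footprints). PSCA, a surface antigen of epithelial cells, had 784 and 3523 FPKM in H1933, against 25.5 and 98.8 FPKM, and ranked 52 in H1933 RNA and 19 in H1933 footprints. The 20 most abundant genes took 18.0% of all FPKM in H1933 footprints and 13.9% in PC9 footprints.

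Runs of neighbouring genes were compared between the lines by the median over the 10 measured genes around each centre gene, with gene order taken from assembly GRCh38.p14. The middle 95% of 10269 runs had median RNA differences between -1.59 and 1.16. Runs were ranked by RNA and footprints together, without overlap. The highest run in PC9 was centred on GABRA3, a receptor subunit for GABA, and held MAGEA3, MAGEA4, MAGEA6, MAGEA12 and CSAG1 (median 4.72 in RNA and 3.78 in footprints). The next lay around TMEM136 (2.14 and 2.24), with the cell adhesion gene MCAM and TRIM29, and around SLC25A12 (1.91 and 2.04), with the integrin gene ITGA6. The lowest runs in PC9 were that around CAPZA2, which holds MET (-2.54 and -2.85), that around PDK4, which holds ASNS (-2.54 and -2.74), that around MRPS28 (-2.65 and -2.47), with the fatty acid binding proteins FABP4 and FABP5, and that around MCM7 (-2.42 and -2.45). The next was that around SMURF1 (-2.33 and -2.34).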
